A study of Mus musculus with 20 samples.

How the data were processed

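Poly(A)-enriched, paired-end libraries with reads of 150 bp were made from mouse brain RNA extracted with a DNase step and sequenced on a NovaSeq6000, per the labels. The estimated counts per gene that the authors deposited were made with RSEM after cutadapt on genome build mm10, per the submitters' processing notes. RSEM shares reads that match several genes by their likelihood, so an estimated count need not be whole, and 4.11% of the values were not. The TPM values the authors deposited (transcript abundances scaled to the same total in every library) come from the same RSEM runs, per the labels. Tool versions, the annotation and the use of strand in counting are not given in the sources used here. Genes that overlap or lie antisense to each other, and near-identical copies, are therefore uncertain.

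The tables held 23845 genes, 4428 of them at 0 in every library. The 20 libraries were assigned to 7 groups from their titles, and library totals ran from 21395046 to 33828756. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): TMM factors (0.975 to 1.03), the filterByExpr filter with the groups, which left 16063 genes, and robust quasi-likelihood fits (glmQLFit, glmQLFTest). All 20 libraries entered 1 fit with a mean per group, so the groups shared an estimate of the spread (common dispersion 0.0144, biological coefficient of variation 0.12). In all, 13 contrasts were tested: each line against Wild type, the 7a against the 7b line of each gene, each of these 4 lines against the lf/lf line of its gene, and the difference between the 2 differences of 7a and 7b. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05, and all tests were two-sided. Values per library are CPM with TMM factors, group values are means with SD, and intervals are 95% intervals from the edgeR fit.

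Gene lists for brain cell types, brain regions, neighbouring tissue and signalling pathways were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, served as checks. Of 35 lists, 34 had at least 4 tested members. The design, lists, alternatives and rule for named genes were fixed before the data were examined. By that rule the text names every called gene where a contrast calls fewer than 10. In contrasts calling more it names those with the largest rises and falls, a mean logCPM of at least 1 and no overlap between the groups' libraries, 12 each way for the isoform lines against Wild type or each other and 5 each way otherwise. Predicted genes may stay undescribed. Mapk8, Mapk9 and Mapk10, the sex and substrain genes, list members past the threshold and called neighbours of Mapk8 and Mapk9 are named as well. Other list members, and the genes of the fits with fewer libraries, were chosen after their values were seen. The share of called genes among the 100 tested genes on each side of Mapk8 and Mapk9 was compared with all others by Fisher's exact test, using GENCODE mouse release 21, in which 15359 tested genes had a position. All coordinates are mm10.

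Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, only the groups of a contrast in the fit, the replicate number as a block, limma with trend on log2(TPM + 1) and log2(TPM + 0.1), and each library left out in turn. Chosen after seeing the data were Rn45s left out, the title number (up to 10 or above) as a term, 2 surrogate variables (sva 3.50.0), and the 3 libraries with the highest pituitary transcripts left out. A sex covariate was not run, since every library carried Y-linked transcripts. Exact permutation tests were run in R, and transcripts were aligned with BLASTN 2.17.0. No pair of replicates differed by as little as sampling noise, so each library counted once.

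The tests were tried on simulated counts with 200 of 16063 genes changed in each of 3 simulations per contrast. The 200 were drawn from genes with a mean logCPM of at least 1, and the members of 1 list were raised 1.2-fold as well. Counts were drawn independently for each gene and library. Differences between libraries that many genes share were not simulated, so the rates may not carry over to the real libraries. For J1 lf/lf against Wild type, 49.3% of 1.4-fold and 94.7% of 2-fold changes were recovered, with 4.83% of calls false. For J17b against Wild type these were 37.3%, 92.7% and 6.17%. Changes of 1.2-fold were recovered in 3.33% and 2% of cases, so most changes of that size would be missed in these 2 contrasts. Other contrasts and fits with fewer groups were not simulated.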

Results

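RNA was sequenced from brains of mice in 20 samples labelled strain C57/Bl6J, in 7 genotype groups. The groups are Wild type, J1 lf/lf, J2 lf/lf, J17a, J27a and J27b with 3 libraries each, and J17b with 2. The series describes single-isoform knockout mice and their controls on a normal diet and set out to characterise the model and its exon usage. The series title names a JNK isoform. JNK1, JNK2 and JNK3 are the stress-activated kinases encoded by Mapk8, Mapk9 and Mapk10, and transcripts of these genes carry 1 of a pair of mutually exclusive exons (the 7a and 7b forms). The labels do not spell out the codes, nor whether the form named in a code was removed or kept, so the groups are called by their labels. Library totals ran from 21395046 to 33828756 estimated counts. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples.

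The JNK genes came first, as the genes the lines are built on. Mapk8 (chromosome 14, 33377898 to 33447158, mm10) stood at 122 ± 16.2 CPM in Wild type (SD, n = 3). It was 76.9 ± 3.21 CPM in J17b (SD, n = 2), 62.9% of Wild type, and its libraries at 74.6 and 79.2 CPM lay below each of the other 18, which ran from 102 to 140 CPM. Mapk8 was 109 ± 4.08 (J27b) to 118 ± 10.3 CPM (J27a) in the remaining groups (SD, n = 3), including 114 ± 10.4 CPM in J1 lf/lf and 109.5 ± 5.79 CPM in J17a. Mapk9 (chromosome 11, 49846751 to 49886421) was 319 ± 36.3 CPM in Wild type and 136 ± 67.1 CPM in J2 lf/lf (SD, n = 3 each). The J2 lf/lf libraries were uneven, at 177, 171 and 58.1 CPM, or 55.5%, 53.7% and 18.2% of the Wild type mean, while every library of the other groups lay between 274 and 360 CPM. Mapk10 (chromosome 5, 102907948 to 103211334) ranged only from 341 to 422 CPM over the 20 libraries. Counts are per gene, so use of the alternative exons was not analysed here, and a normal total in an isoform line does not show which form was made.

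**Figure D1:**
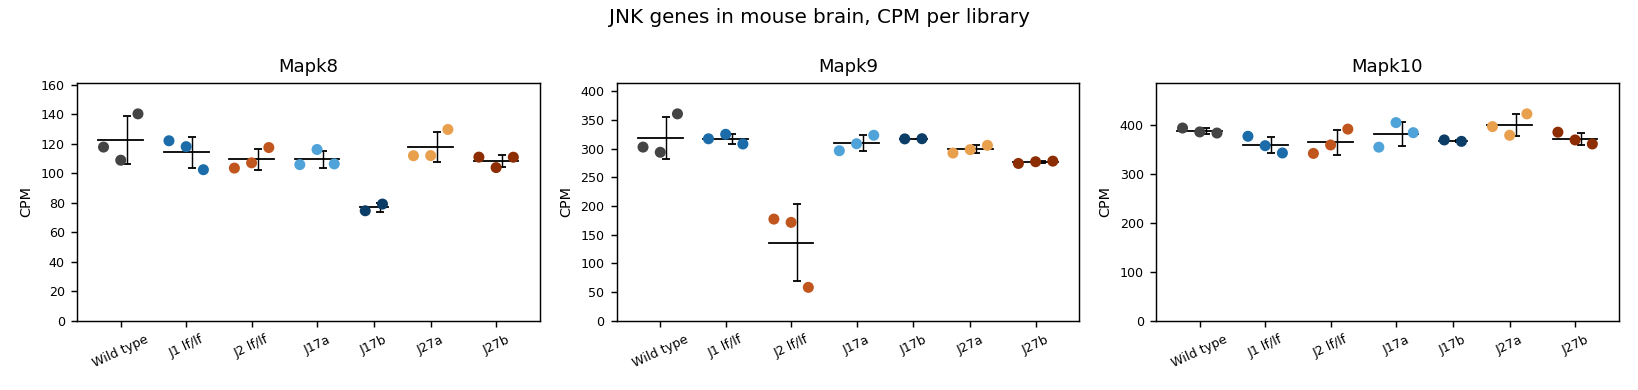
Mapk8, Mapk9 and Mapk10 in CPM (vertical axis, from 0) for each library, grouped by genotype on the horizontal axis; horizontal lines are group means and error bars are SD. Both J17b libraries lie at the bottom of the Mapk8 panel (74.6 and 79.2 CPM), and the J2 lf/lf libraries lie below all others for Mapk9 (58.1 to 177 CPM).

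J1 lf/lf was compared with Wild type as the line whose code names JNK1 without an isoform. Ide, the insulin-degrading metalloprotease, fell to 51.1% of Wild type, from 109 ± 3.92 to 55.7 ± 1.91 CPM (SD, n = 3 each; log2 fold change -0.97 ± 0.09 SE, edgeR adjusted p = 1.55e-05). Btaf1, a TATA-binding protein regulator on the same chromosome, fell to 62.5%, from 65.4 ± 2.81 to 40.9 ± 3.65 CPM (log2 fold change -0.68, SE 0.10, adjusted p = 0.00739). Both were lower in 3 of 3 libraries, and they were the 2 genes called of 16063. Mapk8 was not called (log2 fold change -0.10, 95% interval -0.28 to 0.09, adjusted p = 0.952). Ide and Btaf1 lie on chromosome 19, at 37268743 to 37337852 and 36926079 to 37012752, whereas Mapk8 lies on chromosome 14. Cpeb3 and March5, which sit between them and were chosen after their values were seen, were at 124 ± 6.06 and 92.1 ± 2.33 CPM against 123 ± 5.44 and 92.6 ± 4.2 CPM in Wild type.

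Among the fixed lists, olfactory bulb markers were higher in J1 lf/lf (7 of 8 members positive, camera adjusted p = 7.71e-08, but adjusted p = 0.205 with an estimated correlation). Doc2g, a synaptic protein of mitral cells, had a log2 fold change of 2.87 (SE 0.46) and Tbx21, a mitral cell transcription factor, one of 4.64 (SE 1.04). Adjusted over the list alone 5 of the 8 members were called, and over all genes 0. The list median stood 2.51 and 1.57 log2 units above the median library in J1 lf/lf replicates 2 and 3, and at -0.16 in replicate 1. ER chaperones were lower (10 of 10 negative, camera adjusted p = 1.32e-06, adjusted p = 0.205 with an estimated correlation), with Manf at -0.31 and Pdia4 at -0.32 and 4 of 10 called adjusted over the list alone. Oligodendrocyte genes were higher (9 of 10 positive, median 0.23, adjusted p = 0.288 with an estimated correlation), led by the myelin protein gene Mobp at 0.39, although the median of J1 lf/lf replicate 2 (-0.03) lay below that of Wild type replicate 2 (-0.0021). Camera also called glucocorticoid response genes and immediate early genes lower, synaptic receptors and scaffolds lower, and red blood cell, cholesterol synthesis and choroid plexus genes higher, with adjusted p from 0.288 to 0.708 with an estimated correlation. The red blood cell median was 0.52 and 1.52 in J1 lf/lf replicates 2 and 3 but -0.66 in replicate 1, below each Wild type library. Wild type replicate 3, at -0.37, lay below all 3 J1 lf/lf libraries in the synaptic median. The count of 2 genes became 5, 10, 15 and 1 without Wild type replicate 1, Wild type replicate 3, J1 lf/lf replicate 1 and J1 lf/lf replicate 3. The call of Btaf1 was lost without J1 lf/lf replicate 3 (adjusted p = 0.17), with limma (0.104 and 0.0967), with only the groups of the contrast in the fit (0.447) and without the 3 libraries with the highest pituitary transcripts (0.486). That of Ide held in all of these.

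J2 lf/lf was compared with Wild type in the same way for JNK2. Gt(ROSA)26Sor, the noncoding transcript of the Rosa26 locus that is widely used for gene targeting, was nearly absent: 0.196 ± 0.114 CPM against 5.2 ± 1.05 CPM (SD, n = 3 each; log2 fold change -4.63, SE 0.28, edgeR adjusted p = 1.63e-09). It was lower in 3 of 3 libraries and was the only gene called. It lies on chromosome 6 at 113067428 to 113077333 and overlaps the 3' end of Thumpd3 on the opposite strand. Thumpd3 itself had a log2 fold change of 0.17 (SE 0.12, adjusted p = 0.685), and since the use of strand in counting is not given in the sources used here, reads in the overlap cannot be told apart. Mapk9 was at 42.5% of Wild type (log2 fold change -1.24, SE 0.27, unadjusted p = 0.000417), which missed the threshold over all genes (adjusted p = 0.586) with these 3 uneven libraries. Whether replicate 3, at 18.2% of Wild type, has the same genotype as replicates 1 and 2 is not given in the sources used here, and the group mean stands for 1 genotype only if it does. Without J2 lf/lf replicate 3, the lowest, it passed (-0.87, adjusted p = 3.8e-06), and the DESeq2 Wald test on all libraries gave adjusted p = 0.0148.

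Cholesterol synthesis genes were higher in J2 lf/lf (15 of 16 positive, camera adjusted p = 0.000375, adjusted p = 0.44 with an estimated correlation). Lss, lanosterol synthase, was at 0.41 (SE 0.12) and was the 1 member called adjusted over the list alone. All 12 immediate early genes, the rapid transcriptional response to neuronal activity, were positive, with Arc at 0.77 (SE 0.36) and Nr4a1 at 0.57 (SE 0.25), but 0 were called adjusted over the list alone and adjusted p = 0.746 with an estimated correlation. The immediate early median of J2 lf/lf replicate 1 (0.22) lay below that of Wild type replicate 2 (0.26), and the cholesterol median of J2 lf/lf replicate 2 (0.02) below that of Wild type replicate 3 (0.04). Ependymal genes, of the ciliated cells that line the ventricles, were positive in 6 of 6 (median 0.53, adjusted p = 0.44 with an estimated correlation), and Foxj1 at 0.51 and Rarres2 at 0.54 were called adjusted over the list alone. Camera also called microglial, choroid plexus and oligodendrocyte genes higher and ER chaperones and cerebellar genes lower, with adjusted p from 0.44 to 0.746 with an estimated correlation. The choroid plexus median was 0.97 log2 units above the median library in J2 lf/lf replicate 1. The count of 1 gene became 7, 2 and 2 without Wild type replicate 1, Wild type replicate 2 and J2 lf/lf replicate 3.

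**Figure D2:**
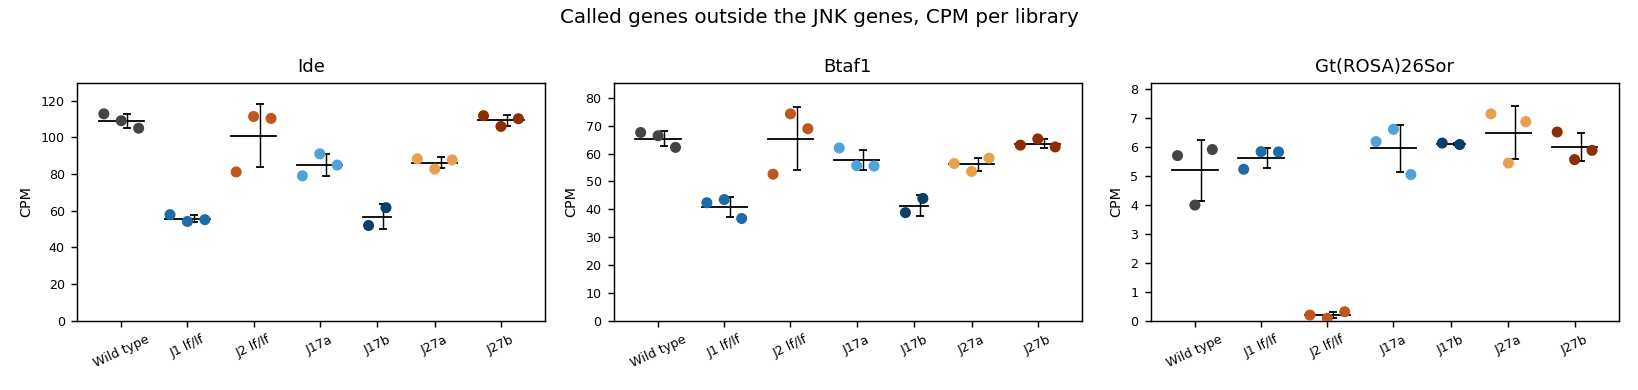
Ide, Btaf1 and Gt(ROSA)26Sor in CPM (vertical axes, from 0) for each library by genotype; lines are group means and error bars SD. Ide runs near 109 CPM in Wild type and J27b, near 85 CPM in J17a and J27a and near 56 CPM in J1 lf/lf and J17b, with 1 J2 lf/lf library at 81.2 CPM; Gt(ROSA)26Sor is near 0 only in J2 lf/lf.

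J17a and J17b are the lines whose codes name an exon 7 form of JNK1. In J17b, 3 genes fell and 1 rose against Wild type. Ide fell to 52.1% of Wild type (56.8 ± 6.88 CPM, SD, n = 2; log2 fold change -0.94, SE 0.11, edgeR adjusted p = 0.000271) and Btaf1 to 63.2% (-0.66, SE 0.11, adjusted p = 0.0442). Mapk8 fell by 0.67 on the log2 scale (SE 0.10, adjusted p = 0.0128), lower in 2 of 2 libraries. Rn45s, the precursor of ribosomal RNA, rose 7.95-fold, from 4909 ± 1581 to 39049 ± 22131 CPM (adjusted p = 0.0443). The libraries were poly(A)-enriched, and whether these counts follow the amount of the precursor in the tissue was not tested. Ide and Btaf1 are also the 2 genes that were lower in J1 lf/lf. Independent lists of these sizes would share 0.000374 genes. Simulations of unchanged groups against the same Wild type libraries made too few calls (a mean of 1.3 over 13 contrasts) to show what shared controls add. The Wild type libraries were not split between the contrasts, but the other lines offer a comparison without them. Ide was 51.9 to 61.7 CPM in the J1 lf/lf and J17b libraries and at least 79 CPM in every library of the other lines. Btaf1 was 36.7 to 43.9 CPM against at least 52.6 CPM. These values argue against shared controls as the source of the lower Ide and Btaf1 in both groups.

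In J17a against Wild type edgeR called 0 genes, with 705 at an unadjusted p under 0.05 where chance gives 803, while DESeq2 called 1 and limma on TPM 0. Mapk8 was at 89.5% of Wild type (-0.16, 95% interval -0.35 to 0.03, adjusted p = 0.993). Ide was at 78% (85 ± 6.01 CPM, SD, n = 3; -0.36, unadjusted p = 0.000885, adjusted p = 0.993), between the Wild type and J17b levels. Directly compared, J17a and J17b differed in 0 genes with edgeR (948 at an unadjusted p under 0.05), 12 with DESeq2 and 0 with limma. Mapk8 was 1.42-fold higher in J17a than in J17b (log2 difference 0.51, 95% interval 0.30 to 0.72, adjusted p = 0.159), and DESeq2 gave adjusted p = 0.00701. Fitted with the groups of that contrast only, 4 genes were called, named after their values were seen: Egr1 (0.78), Fosl2 (0.75) and Ier5 (0.81) higher in J17a, and the metallothionein gene Mt2 (-0.64) lower.

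ER chaperones, the folding machinery of the secretory pathway, were lower in J17b than in Wild type in 10 of 10 members (camera adjusted p = 3.93e-08, adjusted p = 0.0944 with an estimated correlation, fry adjusted p = 0.047). Hspa5, the chaperone BiP, was at -0.31 (SE 0.10), Pdia4 at -0.36 (SE 0.11) and Calr at -0.21 (SE 0.08), and 6 of 10 were called adjusted over the list alone but 0 over all genes. The lower ER chaperones were not particular to J17b. Camera called them lower in J1 lf/lf, J2 lf/lf, J27a and J27b against the same Wild type libraries, whose list medians were 0.18, 0.08 and 0.14. It did not call them in J17b against J1 lf/lf. In J17b against Wild type, glutamatergic neuron genes were negative in 8 of 8 (Neurod6 -0.50, Nrn1 -0.31, both called adjusted over the list alone, adjusted p = 0.479 with an estimated correlation), and heat shock genes in 6 of 6 (adjusted p = 0.393 with an estimated correlation). Wild type replicate 3 lay below J17b replicate 1 in the medians of both lists, at -0.23 against -0.08 and at -0.48 against -0.15, and J17b replicate 2 was the lowest of all libraries for glutamatergic neuron genes (-0.31). Against J17b, J17a had higher immediate early genes (10 of 12 positive, Fosb 0.81 and Egr1 0.78 called adjusted over the list alone, adjusted p = 0.621 with an estimated correlation). The AP-1 and ATF factors, the transcription factors that include the JNK substrates, were positive in 9 of 10 (adjusted p = 0.597 with an estimated correlation), with Fosl2 at 0.75 and Fosb called adjusted over the list alone, while Jun was at -0.14. J17a replicate 2 lay between the J17b libraries in both lists. Its immediate early median was -0.05, against -0.32 and -0.01 in J17b replicates 1 and 2. Its AP-1 and ATF median was -0.12, against -0.09 and -0.27. Camera called 7 further lists in J17a against J17b, with adjusted p from 0.528 to 0.851 with an estimated correlation: ER chaperones, heat shock, cholesterol synthesis, glutamatergic neuron and general neuron genes higher, and cerebellar and choroid plexus genes lower. The cerebellar list median was 0.72 log2 units above the median library in J17b replicate 2, with a choroid plexus median of 0.91 in the same library. Against Wild type, J17a had immediate early, cholesterol synthesis and microglial genes higher and anterior pituitary genes lower by camera, each with adjusted p = 0.828 with an estimated correlation, the last moving with Wild type replicate 2, where pituitary Gh stood at 1008 CPM.

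For J17b against Wild type the count of 4 became 54, 15, 2 and 1 without Wild type replicate 3, J17b replicate 1, Wild type replicate 2 and J17b replicate 2. The call of Mapk8 was lost without J17b replicate 1 (adjusted p = 0.0827) or replicate 2 (0.247), with limma (0.118 and 0.163), with the title number as a term (0.29) and with only the groups of the contrast in the fit (1.00). Btaf1 was lost without Wild type replicate 1 (0.143), Wild type replicate 2 (0.0695), J17b replicate 1 (0.173) or J17b replicate 2 (0.302), and Rn45s without Wild type replicate 1 (0.235), Wild type replicate 2 (0.0695) or J17b replicate 2 (0.831). Over the alternatives that leave out no single library Mapk8 kept its call in 6 of 11, Btaf1 in 4 of 11 and Rn45s in 3 of 10. With the title number as a term the change of Rn45s was 1.55 in place of 2.99 (adjusted p = 0.692). Ide held without each library and was lost with only the groups of the contrast in the fit (adjusted p = 0.73). J17a against Wild type went from 0 to 1 without J17a replicate 2, and J17a against J17b from 0 to 2 without J17a replicate 1. Rn45s was 23400 and 54698 CPM in the J17b libraries, and every library with a title number above 10 had at least 17321 CPM, in all isoform lines.

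**Figure D3:**
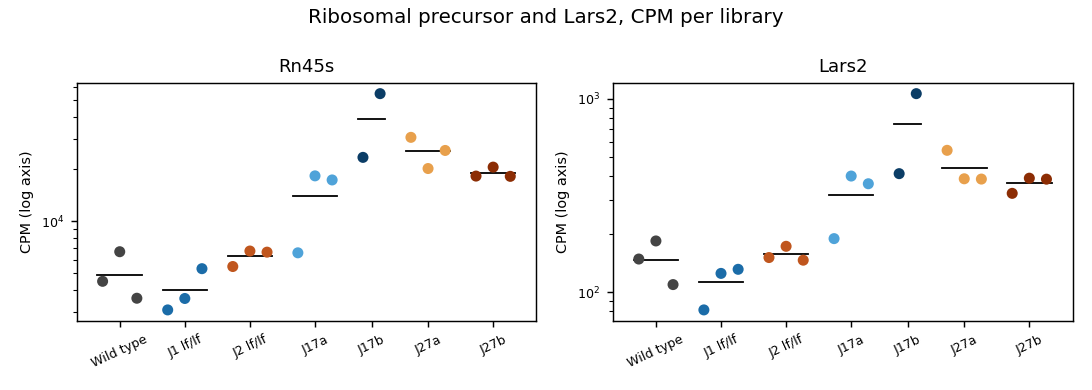
Rn45s and Lars2 in CPM on log axes for each library by genotype; lines are group means. Rn45s lies at 3066 to 6718 CPM in Wild type, J1 lf/lf, J2 lf/lf and J17a replicate 1 and at 17321 to 54698 CPM in the other libraries of the isoform lines.

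J27a and J27b are the lines whose codes name an exon 7 form of JNK2. With all libraries in the edgeR fit, J27a against Wild type gave 0 genes (777 at an unadjusted p under 0.05; DESeq2 5, limma 0) and J27b 0 (1114 unadjusted; DESeq2 7, limma 0). Mapk9 was at 93.7% of Wild type in J27a (299 ± 6.73 CPM) and 86.7% in J27b (276 ± 2.09 CPM, SD, n = 3 each), with log2 fold changes of -0.09 (95% interval -0.66 to 0.47) and -0.21 (-0.77 to 0.36) and adjusted p = 0.976 and 0.88. These intervals rest on the spread over all groups, which includes the uneven J2 lf/lf libraries. The J27b libraries (274 to 278 CPM) lay below each Wild type library (293 to 360 CPM), while those of J27a (292 to 306 CPM) overlapped them. Ide was at 79.1% in J27a (86.3 ± 3.06 CPM; -0.34, unadjusted p = 0.00154, adjusted p = 0.84) and at 100.3% in J27b (109 ± 3.03 CPM). Rn45s was 25461 ± 5196 CPM in J27a and 18987 ± 1354 CPM in J27b (SD, n = 3 each; edgeR adjusted p = 0.771 and 0.598). Fitted with the groups of the contrast only, edgeR called Rn45s in J27a against Wild type (log2 fold change 2.38, SE 0.23, adjusted p = 0.03).

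In J27a, all 10 striatal genes were negative against Wild type, with the dopamine receptor genes Drd2 at -0.67 (SE 0.28) and Drd1 at -0.49 (SE 0.25; camera adjusted p = 9.91e-05, adjusted p = 0.744 with an estimated correlation, 0 adjusted over the list alone). ER chaperones were negative in 10 of 10 in J27a and in J27b (medians -0.16 and -0.18; adjusted p = 0.553 and 0.405 with an estimated correlation), though J27a replicate 1, with a median of 0.12, lay above Wild type replicate 2 (0.08). GABAergic neuron genes were lower in J27b (7 of 8 negative, camera adjusted p = 0.00235, adjusted p = 0.0805 with an estimated correlation, fry adjusted p = 0.0533), with Gad1, which makes GABA, at -0.25 and Lhx6 at -0.35, and 0 called adjusted over the list alone. The GABAergic median was lowest of all libraries in J27b replicate 3 (-0.27) and highest in Wild type replicate 2 (0.15), and Wild type replicate 3 (-0.08) lay below J27b replicate 2 (-0.06). Cerebellar genes were lower in J27b in 8 of 9, with Gabra6 at -0.93 and Neurod1 at -0.77 (adjusted p = 0.735 with an estimated correlation), and the list median was -0.54, -0.37 and -0.35 log2 units from the median library in its 3 libraries. Camera also called choroid plexus and oligodendrocyte genes lower and synaptic receptors and scaffolds higher in J27a (adjusted p = 0.744 with an estimated correlation), and oligodendrocyte genes higher and anterior pituitary, circadian clock and glucocorticoid response genes lower in J27b (adjusted p from 0.735 to 0.914). The synaptic median was -0.37 in Wild type replicate 3 and 0.14 and 0.04 in the other Wild type libraries, against 0.15, 0.05 and 0.18 in J27a. J27a went from 0 to 3 genes and J27b from 0 to 2 without Wild type replicate 1.

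J27a and J27b were then compared with each other. EdgeR called 0 genes with all libraries in the fit (930 at an unadjusted p under 0.05; DESeq2 1, limma 0). The smallest adjusted p was that of Gbx2, a homeobox gene of the thalamus, 2.34 ± 0.493 CPM in J27a and 8.6 ± 0.53 CPM in J27b (SD, n = 3 each; -1.87, SE 0.30, adjusted p = 0.0656). Fitted with these 6 libraries only, whose common dispersion was 0.00672 against 0.0144 over the series, 131 genes were called, 59 higher and 72 lower in J27a; those named here were chosen after their values were seen. The lower ones were led by Slc17a6 (-0.70, SE 0.05, adjusted p = 4.4e-06), the vesicular glutamate transporter of subcortical neurons, with Gbx2 (-1.88), Ntng1 (-0.58), Shox2 (-0.79) and Tcf7l2 (-0.83), and the higher ones included Reln (0.34), Gas7 (0.29) and Nptx1 (0.33). Oligodendrocyte genes were lower in J27a in 10 of 10 (camera adjusted p = 6.47e-12, adjusted p = 0.21 with an estimated correlation), with Opalin at -0.63 and Mag at -0.38, and 7 of 10 were called adjusted over the list alone. Circadian clock genes were higher in 13 of 15 (adjusted p = 0.282 with an estimated correlation), and Per3 at 0.36, Per2 at 0.39 and Tef at 0.20 were called adjusted over the list alone. Cerebellar, GABAergic, synaptic, immediate early and red blood cell genes were also called higher and choroid plexus, ependymal and cholesterol synthesis genes lower, with adjusted p from 0.229 to 0.467 with an estimated correlation. The immediate early median was 0.67 in J27a replicate 3 but -0.14 and -0.23 in replicates 1 and 2. The cerebellar median was -0.44 in J27a replicate 3, against the rise, and 0.63 and 0.29 in replicates 1 and 2. Leaving out any 1 of the 6 libraries from the fit with all libraries left its edgeR count at 0. The 131 genes of the fit with 6 libraries only were not checked in this way.

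The lf/lf lines gave the isoform lines a second reference. J17b against J1 lf/lf called 5 genes, each at adjusted p = 0.0486: Rn45s (3.29, SE 0.44), Lars2 (2.71, SE 0.38), Lrrc58 (0.52, SE 0.09) and 4930488L21Rik (2.94, SE 0.53) rose and Mapk8 fell by 0.57 on the log2 scale (SE 0.10). Lars2, the mitochondrial leucyl-tRNA synthetase, stood at 738 ± 462 CPM in J17b (SD, n = 2) and 113 ± 27.5 CPM in J1 lf/lf (SD, n = 3). J17a against J1 lf/lf called Ide alone, 1.53-fold higher (0.61, SE 0.09, adjusted p = 0.03), whereas Ide was not called between J17b and J1 lf/lf (0.03, 95% interval -0.19 to 0.25). J27a and J27b against J2 lf/lf each called Gt(ROSA)26Sor alone, 30.9-fold and 28.5-fold higher (4.95, SE 0.28, adjusted p = 3.46e-10, and 4.83, SE 0.28, adjusted p = 5.82e-10). Mapk9 was 2.21-fold and 2.04-fold higher than in J2 lf/lf (1.14 and 1.03; adjusted p = 0.42 and 0.566), and without J2 lf/lf replicate 3 it passed in both (0.78 and 0.67; adjusted p = 2.61e-05 and 0.000317).

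Immediate early genes were higher in J17a than in J1 lf/lf (11 of 12 positive, camera adjusted p = 2.64e-12, adjusted p = 0.258 with an estimated correlation), with Arc at 1.56 (SE 0.37) and Egr2 at 1.60 (SE 0.41) and 6 of 12 called adjusted over the list alone. Fitted with those groups only, 8 genes were called, all higher in J17a, among them (chosen after their values were seen) Arc, Egr1, Egr2 and the ERK phosphatase gene Dusp6 (0.58). Immediate early genes were lower in J27b than in J2 lf/lf (10 of 12 negative, adjusted p = 0.314 with an estimated correlation), with Nr4a1 at -0.97 and Arc at -1.30 and 4 of 12 called adjusted over the list alone. In the same comparison Sgk1 (-0.90), Errfi1 (-0.36), Per1 (-0.53) and Pdk4 of the glucocorticoid response list were called lower adjusted over the list alone and Zbtb16 (0.51) and Plin4 higher (adjusted p = 0.563 with an estimated correlation). Fitted with their own groups only, 83 genes were called in J27b against J2 lf/lf, 43 higher and 40 lower, among them (again chosen after their values were seen) Nr4a1 (-0.98), Nr4a3 (-0.83), Ddit4 (-0.75) and Dusp1 (-0.62). In J27a against J2 lf/lf that fit called 28, with Sgk1 (-0.81), Aqp1 (-1.41), Sox10 (-0.39) and Pllp (-0.52) among the 14 lower. The 83 also held Rn45s (1.60), Lars2 (1.22) and Lrrc58 (0.22), higher in J27b, and the 28 held none of these. All J2 lf/lf libraries have title numbers up to 10 and all J27a and J27b libraries numbers above 10. Line and title number therefore cannot be told apart in the 83 and the 28.

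Choroid plexus genes were lower in J27a than in J2 lf/lf in 11 of 11 (median -1.03, camera adjusted p = 3.28e-11, adjusted p = 0.215 with an estimated correlation), with the thyroxine carrier gene Ttr at -1.43 and Aqp1 at -1.41 and 5 called adjusted over the list alone. Oligodendrocyte genes were lower in 10 of 10 (7 called adjusted over the list alone) and cholesterol synthesis genes in 15 of 16, both with adjusted p = 0.158 with an estimated correlation. Red blood cell genes were positive in 4 of 4 (median 0.99, adjusted p = 0.215 with an estimated correlation). The JNK module was called higher by camera in J27a against J2 lf/lf (15 of 20 positive, adjusted p = 0.25 with an estimated correlation), and its 1 member called adjusted over the list alone was Mapk9 itself. Olfactory bulb genes were lower in J17a and J17b than in J1 lf/lf (medians -1.74 and -1.47, adjusted p = 0.258 and 0.401 with an estimated correlation, 5 called adjusted over the list alone in each), moving with the high values of J1 lf/lf replicates 2 and 3. The other lists called in these 4 comparisons had adjusted p from 0.158 to 0.72 with an estimated correlation.

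In these comparisons the counts moved with single libraries. J17a against J1 lf/lf went from 1 gene to 14 and 2 without J1 lf/lf replicate 1 and J17a replicate 1, and to 0 without each of the other 4 libraries, where Ide had adjusted p from 0.154 to 0.187. J17b against J1 lf/lf went from 5 to 25 without J17b replicate 1, to 2 without J1 lf/lf replicate 1 and to 0 without J17b replicate 2, J1 lf/lf replicate 2 or J1 lf/lf replicate 3. The call of Mapk8 was lost without each library (adjusted p from 0.1 to 0.805), and those of Rn45s, Lars2, Lrrc58 and 4930488L21Rik without each library except J17b replicate 1. All J1 lf/lf libraries have title numbers up to 10 and both J17b libraries numbers above 10. With the title number as a term all 5 calls were lost. Rn45s was then at 1.85 (edgeR adjusted p = 0.45), Lars2 at 1.699 (0.495), Lrrc58 at 0.38 (0.664), 4930488L21Rik at 2.74 (0.453) and Mapk8 at -0.64 (0.269). With limma on log2(TPM + 1) 4930488L21Rik was at 1.69 (0.0562). All 5 calls were also lost with only the groups of the contrast in the fit (adjusted p from 0.136 to 0.93). Without Rn45s the other 4 had adjusted p = 0.0616. J27a against J2 lf/lf went from 1 to 2 without J2 lf/lf replicate 3 or J27a replicate 1, and J27b against J2 lf/lf from 1 to 2 without J2 lf/lf replicate 3 or J27b replicate 3, and Gt(ROSA)26Sor held without each library.

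Whether the difference between the 7a and 7b lines was the same for JNK1 and JNK2 was tested as a difference of differences. Ide alone differed (0.92, SE 0.14, adjusted p = 0.0267): it was higher in J17a than in J17b by 0.58 (SE 0.11) and lower in J27a than in J27b by 0.34, with a log2 difference of -0.34 (SE 0.09). Mapk8 gave 0.39 (95% interval 0.11 to 0.67, adjusted p = 0.564) and Mapk9 -0.15 (SE 0.40, adjusted p = 0.986). Cerebellar genes had the smallest camera p of the lists (8 of 9 negative, median -1.16, camera adjusted p = 1.83e-07, adjusted p = 0.543 with an estimated correlation), with Cbln3 at -1.36 and Neurod1 at -1.24 and 7 called adjusted over the list alone. Camera also called oligodendrocyte, cholesterol synthesis, heat shock, ER chaperone, nuclear respiratory chain, striatal and neuronal genes positive and circadian clock and anterior pituitary genes (median -7.90) negative, with adjusted p from 0.543 to 0.658 with an estimated correlation. The pituitary value moved with J27a replicate 3 (list median 6.05, against 0 and -0.45 in the other J27a libraries) and J17b replicate 2 (1.82). The cerebellar median was 0.62 in J17a replicate 1 and -0.44 in J27a replicate 3, each apart from the other libraries of its group. The count of 1 became 11 without J17a replicate 1 and 2 without J17b replicate 2, and 0 without each of the other 9 libraries, where Ide had adjusted p from 0.0745 to 0.165.

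Over the 13 comparisons camera made 99 list calls, of which 0 held with an estimated correlation, while fry called 1, the ER chaperones in J17b against Wild type. Camera called that list lower against Wild type in J1 lf/lf, J2 lf/lf, J27a and J27b as well. In the 12 comparisons of a pair of groups the library medians of the groups overlapped in 59 of 89 list calls. The JNK module was called in 1 comparison, vascular cell genes and thyroid hormone response genes each in J17a against J1 lf/lf and meningeal fibroblast genes in J17b against J1 lf/lf. Astrocyte genes were called in none (smallest camera adjusted p = 0.324), nor were oligodendrocyte precursor (0.134), hypothalamic (0.254), immature neuron and dividing cell (0.134), insulin and IGF signalling (0.062), integrated stress response (0.134), interferon response (0.0949) or inflammatory mediator genes (0.373). Hippocampal genes were called lower in J27a against J2 lf/lf (7 of 8 negative, adjusted p = 0.25 with an estimated correlation), with the list median at -0.66 in J27a replicate 3 and 0.03 in replicates 1 and 2. Mitochondrially encoded genes were in the fixed lists with 0 members measured.

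Region and tissue markers differed between libraries of the same group. The pituitary hormone genes Gh and Prl reached 2372 and 480 CPM in J1 lf/lf replicate 3, 1008 and 188 CPM in Wild type replicate 2 and 459 and 92 CPM in J27a replicate 3, and in the other 17 libraries Gh was at most 67.5 CPM. Olfactory Doc2g was 21.1 CPM in its highest library, J1 lf/lf replicate 2, against a median of 2.18 CPM over the libraries. The cerebellar median ran from -0.54 in J27b replicate 1 to 0.72 in J17b replicate 2, and the hypothalamic one from -1.87 in Wild type replicate 2 to 1.01 in J2 lf/lf replicate 1. Wild type replicate 3 stood apart from the other Wild type libraries, with a chi-square per gene of 48.6 and 58.9 against them, where other replicate pairs gave 5.26 to 34. Without the 3 libraries with the highest pituitary transcripts, which keeps in J2 lf/lf replicate 2 with Gh at 67.5 CPM, an alternative chosen after seeing the data, the count fell to 1 in J1 lf/lf, stayed at 1 in J2 lf/lf and became 2 in J17b against Wild type. It became 0 in J17a and 1 in J17b against J1 lf/lf and 0 for the difference of differences.

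**Figure D4:**
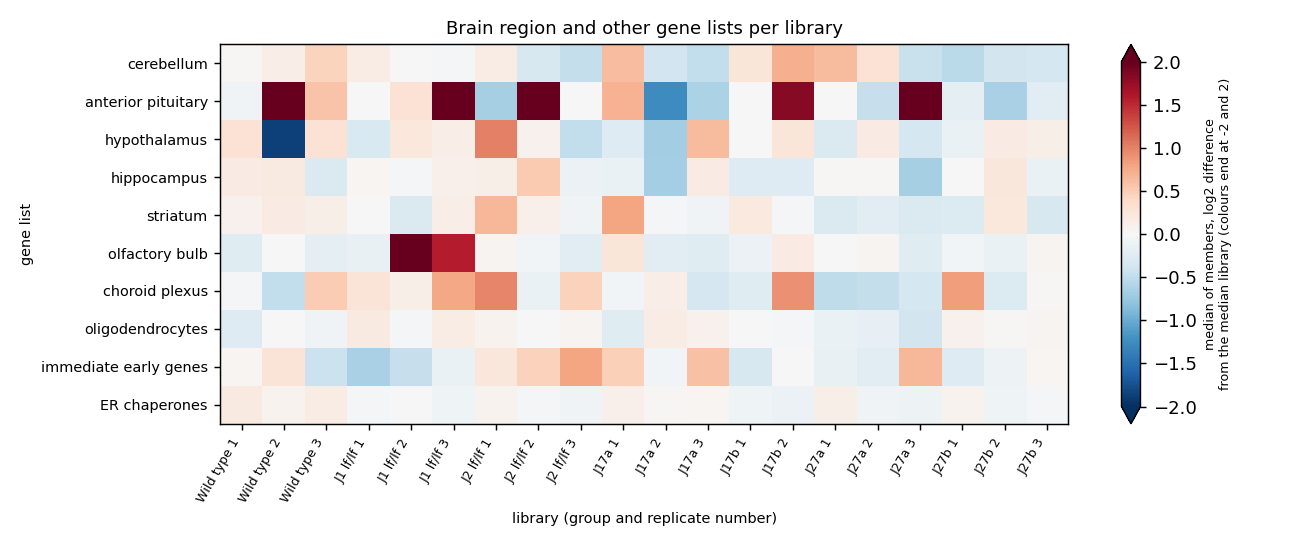
Median of each gene list (rows of the map) in each library (columns), as the log2 difference from the median library, on a colour scale from -2 to 2 where larger values take the end colour. The anterior pituitary list takes the end colour in Wild type 2 (8.21), J1 lf/lf 3 (7.39), J27a 3 (6.05) and J2 lf/lf 2 (3.00). The olfactory bulb list does so in J1 lf/lf 2 (2.51) but not in J1 lf/lf 3 (1.57), and the cerebellar list varies within groups.

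All 20 libraries carried Y-linked transcripts, with Ddx3y at 68.2 to 94 CPM, and Xist at no more than 0.447 CPM, so sex did not separate the groups. Of the genes fixed as differing between C57BL/6 substrains, Nnt had group means from 16.8 to 19.3 CPM, Wdfy1 from 14.4 to 17.9 CPM and Entpd4 from 143 to 168 CPM, with no call in any comparison with all libraries in the fit. Fgfbp3 (chromosome 19, 36917550 to 36919615), the neighbour of Btaf1, ran from 5.47 ± 0.256 CPM in J17b (SD, n = 2) to 11 ± 1.19 CPM in J27b (SD, n = 3). It was not called with all libraries in the fit. With only J27a and J27b in the fit it was called lower in J27a (-0.68, SE 0.13, edgeR adjusted p = 0.0197), as was Ide (-0.34, adjusted p = 0.00555). Among the 100 tested genes nearest on each side of Mapk8 and of Mapk9, 0 were called. With at most 4 called genes elsewhere in any comparison this count could hardly differ. The share at an unadjusted edgeR p under 0.05 did not pass either (two-sided Fisher's exact test, 26 tests, smallest p = 0.0698, adjusted p = 0.854).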

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

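The tests in this part were chosen after the results they bear on were seen, except the difference of differences itself. The difference in Ide between the 7a and 7b lines was not the same for JNK1 as for JNK2, which is what singled it out: the log2 difference of differences was 0.92 (SE 0.14, edgeR adjusted p = 0.0267). The call was lost in 13 of 22 alternatives, counting each library left out, with adjusted p from 3.24e-05 to 0.348 over all of them. The log2 value ran from 0.805 to 1.05 over the libraries left out and from 0.883 to 0.974 over the other alternatives.

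Ide and Btaf1 were lower in J1 lf/lf and J17b, and Ide lay between in J17a and J27a and, within 1 line, in J2 lf/lf replicate 1 (Ide 81.2 CPM against 111 and 110 in replicates 2 and 3, Btaf1 52.6 against 74.3 and 68.9). A genotype effect of Mapk8 as the cause in every line with lower Ide is argued against by J27a, a line labelled for JNK2. There Ide differed from Wild type by -0.34 (SE 0.09, edgeR unadjusted p = 0.00154, adjusted p = 0.84), which was not a call. It could not decide about J1 lf/lf and J17b themselves, since J27a may have a cause of its own. A library batch split at title number 10 is argued against by the difference of -0.97 between J1 lf/lf and Wild type, all with title numbers up to 10. The labels name no batch. Title numbers run group by group there, so any other batch could not be told apart from genotype. A candidate explanation is a variant of the chromosome 19 segment carried in some lines, as a copy-number variant at Ide and Fgfbp3 is known among C57BL/6J mice. Fgfbp3 leaves it open. Its log2 difference between the 5 libraries of J1 lf/lf and J17b and the other 15 was -0.49. The two-sided exact permutation p was 0.0228 over single libraries. An exact permutation of group means gave p = 0.143 over 21 choices of 2 of the 7 (the smallest these allow is 0.0476). Both set J17a and J27a, where Ide lay between, among the others, so they could not decide about a variant carried there too. Mean Fgfbp3 was 6.26 ± 1.13 CPM in J17a (SD, n = 3), 6.89 in J27a, 6.33 in J1 lf/lf and 5.47 in J17b. It was 8.66 in Wild type, 10.1 in J2 lf/lf and 11 in J27b. That grouping by Ide was not tested. Wild type replicate 3 went the other way, with Fgfbp3 at 5.59 CPM and Ide at 105 CPM. Cpeb3 and March5, which lie between Btaf1 and Ide, moved by at most 0.04 in J1 lf/lf or J17b. This argues against an unbroken change of copy number from Btaf1 to Ide. It does not bear on a variant that leaves Cpeb3 and March5 out.

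Gt(ROSA)26Sor was nearly absent in all 3 J2 lf/lf libraries. Wild type tissue mixed into replicates 1 and 2 is argued against, since their Mapk9 would need a share of 43.4% and Gt(ROSA)26Sor stood at 3.75% and 1.59% of the Wild type mean (5.96% in replicate 3). An altered Rosa26 locus in this line, such as an inserted transgene, may explain the loss. Among the 19 other tested genes within 500 kb with a mean logCPM of at least 1, the largest change was 0.23 on the log2 scale. Any cause confined to this transcript would leave its neighbours as they were, so this could not decide between causes. The labels name no inserted transgene, and no other biological explanation was tested.

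Rn45s was 3066 to 6718 CPM in the 10 libraries with title numbers up to 10 and 17321 to 54698 CPM in the 10 above, and Lars2 81.3 to 190 against 325 to 1064 CPM. The change of Lars2 in J17b against J1 lf/lf was 2.71 with Rn45s in (SE 0.383, edgeR adjusted p = 0.0486) and 2.71 with it out (SE 0.385, adjusted p = 0.0616). Leaving Rn45s out could not decide whether a few genes taking the counts was the cause, since TMM factors already allow for such genes. Their shares do bear on Lars2. Rn45s held at most 5.33% of the counts of a library and the 10 highest genes at most 7.95% (both J17b replicate 2). Counts taken by other genes would lower Lars2, whereas it rose, which argues against this explanation for Lars2. A library batch and the genotype of the isoform lines cannot be told apart, because J17a is the only group on both sides. Within it Rn45s was 1.44 log2 units higher above title number 10. The side up to 10 there is replicate 1 alone, at 6560 CPM. The cut was chosen after these values were seen, so this difference restates the pattern.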

How the results depend on the processing

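Leaving out Rn45s, the title number term, the surrogate variables and leaving out the pituitary libraries were chosen after seeing the data; the other alternatives were planned. DESeq2 size factors left all 13 counts within 1.5 times. Of the gene values under alternatives, 368 kept their direction and side of the threshold, 102 lost the call, 7 gained it and 2 turned, both near 0 and without Wild type replicate 3: Mapk8 in J1 lf/lf against Wild type (0.0114, and from -0.176 to 0.0114 over the libraries left out) and Mapk9 in J27a against Wild type (0.00283, and from -0.151 to 0.00283). Ide in J1 lf/lf and Gt(ROSA)26Sor in J2 lf/lf against Wild type kept their calls in all 17 alternatives each (highest adjusted p 0.0122 and 0.00668). Over alternatives the edgeR, DESeq2 or limma adjusted p of Mapk8 in J17b against Wild type ran from 3.48e-06 to 1, of Btaf1 there from 0.000137 to 1 and of Mapk9 in J2 lf/lf against Wild type from 3.8e-06 to 0.909. Unless a construction shows it, the cause of a changed count was not tested.

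The DESeq2 Wald test called 17 genes in J1 lf/lf, 13 in J2 lf/lf, 1 in J17a, 16 in J17b, 5 in J27a and 7 in J27b against Wild type. It called 12 in J17a against J17b, 1 in J27a against J27b, 31 and 23 in J17a and J17b against J1 lf/lf, 26 and 17 in J27a and J27b against J2 lf/lf, and 17 for the difference of differences. With no filter on low counts J27a against J27b gave 1 and J27a against J2 lf/lf 2.

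With only the groups of the contrast in the fit, and so fewer libraries, the counts were 1 in J1 lf/lf, 0 in J17b and 1 in J27a against Wild type, 4 in J17a against J17b and 131 in J27a against J27b. They were 8 and 0 in J17a and J17b against J1 lf/lf and 28 and 83 in J27a and J27b against J2 lf/lf. The zeros are edgeR counts, where the fit with all libraries gave 939 and 678 genes at an unadjusted p under 0.05.

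The limma fit on log2(TPM + 1) gave 1 in J1 lf/lf and 1 in J17b against Wild type, 0 and 2 in J17a and J17b against J1 lf/lf, 4 and 2 in J27a and J27b against J2 lf/lf, and 0 for the difference of differences. On log2(TPM + 0.1) these were 1, 1, 0, 2, 3, 1 and 0.

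Without Rn45s, J17b gave 2 against Wild type and 0 against J1 lf/lf. With the title number as a term the counts were 2 in J17b against Wild type, 2 in J17a against J17b, 1 in J27a against J27b, 0 and 0 in J17a and J17b against J1 lf/lf, and 11 for the difference of differences. With 2 surrogate variables they were 2, 13, 1 and 3 in J2 lf/lf, J17b, J27a and J27b against Wild type, 13 in J17a against J17b, 11 in J17a against J1 lf/lf, 8 and 4 in J27a and J27b against J2 lf/lf, and 3 for the difference of differences. Without the pituitary libraries they were 1 and 2 in J1 lf/lf and J17b against Wild type, 0 and 1 in J17a and J17b against J1 lf/lf, and 0 for the difference of differences.

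Leaving out each library in turn gave 1 to 15 genes in J1 lf/lf, 1 to 7 in J2 lf/lf, 0 to 1 in J17a, 1 to 54 in J17b, 0 to 3 in J27a and 0 to 2 in J27b against Wild type. The ranges were 0 to 2 in J17a against J17b, 0 to 0 in J27a against J27b, 0 to 14 and 0 to 25 in J17a and J17b against J1 lf/lf, 1 to 2 in J27a and J27b against J2 lf/lf, and 0 to 11 for the difference of differences. The highest came without J1 lf/lf replicate 1 (15 and 14), Wild type replicate 1 (7, 3 and 2), Wild type replicate 3 (54), J17b replicate 1 (25) and J17a replicate 1 (11). J17b without 1 library is a lone sample assumed to vary like the other groups.

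The replicate numbers did not pair the samples: over 57 pairs with the same number the correlation of deviations averaged -0.0088, with 2 above 0.1, and 4 of 20 libraries correlated best with their own number. With the replicate block 14 genes were called over the contrasts in place of 16, with 1 in J17b against Wild type, 2 in J17a against J1 lf/lf, 2 and 2 in J27a and J27b against J2 lf/lf and 0 for the difference of differences. Under the block Mapk8 in J17b had an adjusted p of 0.0598 against Wild type and 0.148 against J1 lf/lf. The 99 list calls by camera became 101 with the block, 0 with an estimated correlation and 1 by fry. Windows of 50 and 200 genes beside Mapk8 and Mapk9 held 0 called genes (edgeR), with few called genes anywhere.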

Other observations

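In this part, the fits with fewer groups were planned, the splits of the samples were planned, and the genes named and the sequence alignment were chosen after the results were seen. Some genes were called with the groups of the contrast alone in the fit and are given singly, since no list of such genes was tested. Tph2, which makes serotonin in the brain, was higher in J27a than in J2 lf/lf (log2 fold change 1.36, SE 0.24, edgeR adjusted p = 0.035), and the serotonin transporter gene Slc6a4 was higher in J27b than in J2 lf/lf (1.26, SE 0.25, adjusted p = 0.0249). Hoxb3 and Hoxd3, homeobox genes, were higher in J27b than in J2 lf/lf (1.54 and 1.98, adjusted p = 0.0161 and 0.0201), and Hoxb3 was lower in J27a than in J27b (-1.73, adjusted p = 0.00555). These genes varied within groups: over the J1 lf/lf libraries Tph2 ran from 2.73 to 12.8 CPM and Slc6a4 from 1.06 to 5.34 CPM, and over the J17a libraries Hoxb3 ran from 0.532 to 5.63 CPM and Hoxd3 from 0.399 to 2.92 CPM. With all 20 libraries in the fit none of these passed (adjusted p from 0.763 to 1). Line and title number (up to 10 or above) cannot be told apart in the comparisons with J2 lf/lf.

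Malat1, a nuclear noncoding RNA, ran from 593 to 1147 CPM in the 10 libraries with title numbers up to 10 and from 1159 to 4698 CPM in the 10 above. The longest transcripts of Lars2, Lrrc58, 4930488L21Rik and Malat1 gave 0 aligned bases against the mitochondrial ribosomal RNA genes. They were not aligned against Rn45s.

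The 6 libraries of 2 groups of 3 can be split in 10 ways, too few for a share under 0.05. The real split and the highest of the others gave 2 and 2 genes for J1 lf/lf against Wild type, where 2 splits gave as many, and 1 and 0 for J2 lf/lf against Wild type, J17a against J1 lf/lf, J27a against J2 lf/lf and J27b against J2 lf/lf, where 1 split did. For J27a and J27b against Wild type they gave 0 and 1, for J27a against J27b 0 and 0, and for J17a against Wild type 0 and 715, and all 10 splits gave at least as many where the real count was 0. These zeros are edgeR counts, with 777, 1114, 930 and 705 genes at an unadjusted p under 0.05 and 5, 7, 1 and 1 called by DESeq2. The split with 715 set J17a replicate 1 and Wild type replicates 1 and 2 against Wild type replicate 3 and J17a replicates 2 and 3, which points to a structure of the samples across the groups. Wild type replicate 3 differed from the other Wild type libraries by a chi-square per gene of 48.6 and 58.9.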
